A study of Homo sapiens with 4 samples.

How the data were processed

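SNB-19 glioma cells, grown in medium with 10% serum, were transfected by a lipid reagent with a miR-182 mimic or a negative control mimic, 2 samples each, and RNA was taken after 36 hours, per the labels. The series describes the replicates as biological; the p-values measure the spread between these samples. Cy3-labelled RNA was hybridised to Agilent arrays of design 014850.

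The spot intensities were read by Agilent Feature Extraction version 10.7.3.1 as a one-colour assay, with background subtraction and spatial detrending, per the file headers. These deposited intensities were not scaled between arrays. Each array held 45015 spots, 41000 distinct gene probes and 0 saturated spots. The 75th percentile of the processed intensity was 2027 and 1949 on the control arrays and 2090 and 1932 on the miR-182 arrays, against median local backgrounds of 35.5, 37, 38 and 37.5. The number of arrays limits the precision. The authors also deposited a table of processed log2 values, whose making is not given in the sources used here. Each of its columns correlated above 0.999 with the scanner values treated as described next and centred on each probe's median over the 4 arrays. A correlation does not test shift or scale. The median difference per array was -0.0048 to 0.0048, so the columns lie close to log2 values shifted by each array's 75th percentile. Of its probes 100% had a median under 0.0001 in size, which shows the centring. Its column medians were -0.018 and 0.00059 for the controls and 0.0060 and 0.013 for the miR-182 arrays. The median log2 fold change of the NF-kB target genes tested below was 0.545 with the authors' values and 0.542 with the scanner values. Scale, centring and direction were thereby settled.

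From the scanner values, log2 of the processed intensity minus each array's 75th percentile over gene probes was used. Control spots and spots with an outlier flag (63 to 116 per array) were left out, and spots of 1 probe were averaged. A total of 30 probes without a value on every array were dropped, and 31238 probes well above background on both arrays of at least 1 group were kept. Probes were named by their RefSeq accession, without version, through a RefSeq gene table of a later assembly than the hg19 build of the array design, and no coordinates are given for that reason. Of 27130 probes with a RefSeq accession 26386 were named, and the other 14614 of the 41000 probes keep the name in the file. A gene was read on its brightest kept probe; 5673 genes had several, and of 169 called genes with another kept probe 13 had one of the opposite sign. This left 23770 genes, 14700 of them named; of the calls, 282 that rose and 221 that fell were named.

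The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene comes from limma, and every error beside a log2 fold change is the SE of that fit, with 2 residual degrees of freedom plus a prior of 2.56. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333. A gene not well above background on either array of a group has only a bound: the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the gene's own signal and the lowest signal among probes well above background. The adjusted p of such a gene belongs to its fitted change, which uses signals not well above background, and does not test the bound. Slide and scan were the same for all arrays, so no batch was fitted.

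The rules and 21 gene lists were fixed before the data were examined. Genes were named by 3 rules: the 12 largest rises and 12 largest falls among called genes with separate groups and a signal well above background on both arrays of the brighter group; CYLD, whatever its value; and up to 4 members of each list with the smallest p. Any other gene is said to have been chosen after its values were seen. Some genes that these rules select are not reported here. The list of reported miR-182 targets came from the literature and was not drawn from the values of these arrays. Its member CYLD, however, is known as a target from the study of this series. Lists share members, such as CXCL10, EPAS1, MTSS1 and BCL2L12. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance.

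The alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50 followed by quantile normalization, the authors' processed values, no filter on dim probes, a filter on all 4 arrays, the mean of a gene's probes, probe-level tests, other variance models, stricter thresholds, the replicate number as a block, and leaving out each array. The mean signal that normexp was meant to use is not among the columns used here, so the median spot signal took its place, a choice made after seeing the data. Values given "with normexp" therefore differ from the main ones in signal column, background correction and normalization together. A test of genes with sites for the miR-182 seed was planned and not run, since no 3' UTR sequence was used here.

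The procedure was tested on simulated data for this comparison of 23770 genes, 200 of them changed, 50 at each fold. It called 0% of those changed 1.5-fold, 2% of those changed 2-fold, 76% of those changed 4-fold and 76% of those changed 8-fold, with 3 false calls. The arrays themselves gave 702 calls, far more than the 200 genes changed here, so the adjusted threshold was stricter in the simulation. These shares therefore do not carry over to the arrays, where some genes that differed less than 2-fold were called. A list shifted by 0.6 log2 units was called by camera with a preset correlation (adjusted p = 2.32e-24) with 0 other lists called, and not with an estimated correlation (adjusted p = 0.140). A list that does not pass with an estimated correlation may therefore still have shifted. Simulated genes were drawn independently, so the 0 other lists say little about genes that move together.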

Results

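The series asked how a miR-182 mimic alters gene expression in SNB-19 cells, an established human glioma line. Cells were transfected with an oligonucleotide mimic of the microRNA miR-182 or with a microRNA mimic that served as the negative control, and total RNA was taken 36 hours later. Each of the 2 groups held 2 samples that the series describes as biological replicates, and each sample was hybridised to a one-colour Agilent expression array. Between 30667 and 32738 of the 41000 gene probes were well above background on an array, which is 74.8% to 79.9% of them. Across genes, the 2 control arrays correlated at r = 0.996 and the 2 miR-182 arrays at r = 0.992 (genes are not independent replicates). The SD of the log2 difference between 2 arrays was 0.30 for the controls and 0.41 for the miR-182 arrays, against 0.45 to 0.57 for arrays of different groups. All arrays lay on 1 slide read in 1 scan, with the controls at positions 1 and 2 and the miR-182 samples at positions 3 and 4, so position on the slide and treatment cannot be told apart.

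After the miR-182 mimic, NF-kB target genes were higher as a group (median log2 fold change 0.54 over 36 genes) and genes reported as miR-182 targets were lower (-0.39 over 33). Both lists passed camera with a preset correlation (adjusted p = 1.42e-09 and 1.75e-04), and neither did with an estimated correlation (adjusted p = 0.537 for each). With an estimated correlation camera also missed a list shifted in simulated data, so not passing there decides little. The collagenase gene MMP13 rose 8.43-fold (log2 fold change 3.08 ± 0.12, SE, n = 2 against 2; limma adjusted p = 0.0174). The chemokine gene CXCL10 rose 7.40-fold (2.89 ± 0.12) and IL11, a cytokine of the interleukin-6 family, 6.99-fold (2.80 ± 0.23). In the other direction SCRG1 fell 10.5-fold (-3.40 ± 0.12, adjusted p = 0.0171), and GFAP, the intermediate filament gene of astrocytes, fell 8.30-fold (-3.05 ± 0.15, adjusted p = 0.0192). In all, limma called 702 of 23770 genes at an adjusted p under 0.05, of which 377 rose and 325 fell, and 531 of the 702 differed at least 2-fold. The groups did not overlap in any of the 702, but they were also separate in 53.5% of all genes tested, where chance alone gives 33.3%. The calls rested on the pooled spread of few arrays: limma called 42 genes without control replicate 1, 82 without control replicate 2, 316 without miR-182 replicate 1 and 1051 without miR-182 replicate 2. Of 75 called genes followed through these 4 fits, 51, 47, 22 and 5 lost the call, in that order, but MMP13, CXCL10, IL11, CXCL8, SCRG1 and GFAP passed in each. With no filter on dim probes limma called 0 genes, and an unmoderated linear model also called 0, although 4904 and 4318 genes had an unadjusted p under 0.05. All 702 kept their direction in both, which says little, since neither setting alters the fold change of a given probe.

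**Figure D1:**
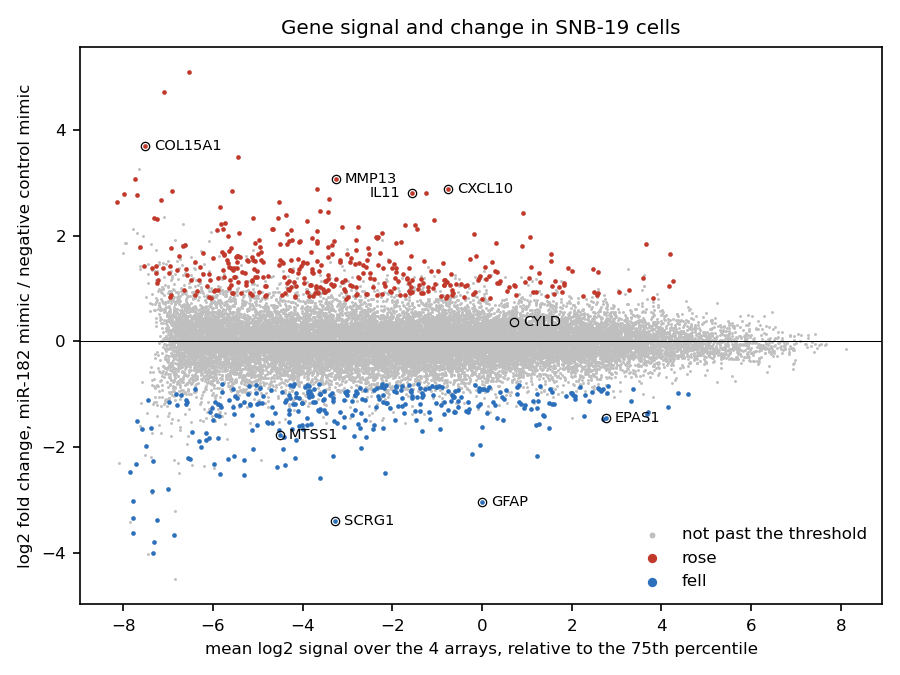
Each point is 1 gene, with its mean log2 signal over the 4 arrays relative to the 75th percentile on the x axis and its log2 fold change, miR-182 mimic over negative control mimic, on the y axis; genes below background in 1 group are drawn at their fitted value. Red points are the 377 genes that rose, blue points the 325 that fell, and the labelled genes include GFAP at -3.05 and MMP13 at 3.08.

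Several of the genes with the largest changes were not well above background in one of the groups, so that the change has only a lower bound. ADGRG4, an adhesion G protein-coupled receptor, was at least 5.78-fold higher on the miR-182 arrays. Its limma adjusted p of 0.0171 belongs to the fitted log2 fold change of 4.73, which uses control signals not well above background. The collagen chain COL15A1 was at least 3.02-fold higher and the gluconeogenic enzyme gene FBP1 at least 2.07-fold higher. MYPN, which encodes a sarcomeric protein, rose 7.22-fold (2.85 ± 0.23), with a signal well above background on 1 of the 2 control arrays. On the falling side SOX6, a transcription factor, was at least 2.55-fold lower after the miR-182 mimic, the secreted glycoprotein gene OLFM4 at least 2.03-fold lower and TSGA10IP at least 3.36-fold lower. Of the 12 largest rises 4 came from probes with no gene name here, the strongest of them ENST00000367073 (at least 9.62-fold higher), and of the 12 largest falls 7 did, among them NR_027378 (at least 4.79-fold lower). The bound was all that could be given for 32 of the genes that rose and 21 of those that fell.

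Genes reported as miR-182 targets in the literature were lower as a group. Of the 33 measured, 5 fell and 0 rose (2 were higher at an unadjusted p under 0.05), and 25 had a log2 fold change below 0, with a median of -0.39. MTSS1, a scaffold of the actin cytoskeleton, fell 3.42-fold (-1.77 ± 0.12, adjusted p = 0.0223), and the retinoic acid receptor RARG 2.81-fold (-1.49 ± 0.15), although the second probe of RARG gave -0.30. The hypoxia-inducible transcription factor EPAS1 fell 2.74-fold (-1.45 ± 0.16), the apoptosis regulator BCL2L12 2.60-fold (-1.38 ± 0.17) and the adenylate cyclase ADCY6 2.24-fold (-1.16 ± 0.12). MITF (-0.70 ± 0.12), PDCD4 (-0.63 ± 0.12) and FOXO1 (-0.49 ± 0.12) were not past the threshold over all genes, with adjusted p of 0.0612, 0.0710 and 0.110. ULBP2 had the highest value of the list, 0.74 ± 0.12 (adjusted p = 0.0593). Other reported targets hardly moved, such as FOXO3 (0.15 ± 0.28, adjusted p = 0.803) and BRCA1 (0.0072 ± 0.12, adjusted p = 0.979). The genes from MITF to BRCA1 were chosen after their values were seen. Adjusted over the list alone, 11 members were lower and 1 higher. The list passed camera, limma's test of a list against all other genes, with a preset correlation (adjusted p = 1.75e-04 over 21 lists), and it did not pass with an estimated correlation (adjusted p = 0.537). The list median was -0.41 without control replicate 1 and -0.37 without control replicate 2. The calls of single members, by contrast, rested on having both control arrays.

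CYLD, a deubiquitinase that restrains NF-kB signalling and a miR-182 target known from work on this system, was not lower at the RNA level. Its log2 fold change was 0.36 ± 0.14 (95% interval -0.0034 to 0.72, adjusted p = 0.225), and its second probe gave 0.0046. Among 20 negative regulators of NF-kB, limma called 0, with 6 at an unadjusted p under 0.05 and a list median of 0.0068 (camera adjusted p = 0.755). Adjusted over the list alone, 1 was higher and 1 lower. The smallest p belonged to N4BP1 (-0.96 ± 0.15, adjusted p = 0.0529), whose second probe gave 0.17, and to TNFAIP3 (0.96 ± 0.17, adjusted p = 0.0647), whose second probe gave 1.44. COMMD1 was at -0.54 ± 0.13 and ITCH at 0.51 ± 0.15, with a second ITCH probe at -0.56.

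NF-kB target genes were higher after the miR-182 mimic. Of 36 measured, 9 rose, 0 fell (2 were lower at an unadjusted p under 0.05) and 31 lay above 0, with a median log2 fold change of 0.54. Besides CXCL10, the neutrophil chemokine gene CXCL8 rose 5.54-fold (2.47 ± 0.15), the growth factor gene CSF2 4.72-fold (2.24 ± 0.15) and the cytokine gene IL1B 3.63-fold (1.86 ± 0.13). The apoptosis inhibitor BIRC3 rose 2.00-fold (1.00 ± 0.12). The other 4 that rose, ICAM1 (1.82 ± 0.15), TNFAIP6 (1.53 ± 0.18), IL1A (1.22 ± 0.12) and LIF (1.12 ± 0.16), are named after their values were seen. CXCL1, chosen in the same way, went the other way: it was not well above background on the miR-182 arrays, at least 3.65-fold lower there, and not past the threshold (adjusted p = 0.0627), with log2 signals of -6.41 and -4.45 on the control arrays. Not every member moved, and those named next were also chosen after their values were seen. NFKBIA (-0.046 ± 0.17, adjusted p = 0.905), NFKB1 (-0.10 ± 0.13, adjusted p = 0.699) and BCL3 (0.073 ± 0.17, adjusted p = 0.844) hardly changed. BCL2A1 was lower without passing the threshold (-0.65 ± 0.22, adjusted p = 0.184). Adjusted over the list alone, 19 members were higher and 1 lower. Camera gave an adjusted p of 1.42e-09, and an adjusted p of 0.537 with an estimated correlation. The fit called 3 members without control replicate 1 (2 higher, 1 lower) and 4 without control replicate 2 (3 higher, 1 lower).

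**Figure D2:**
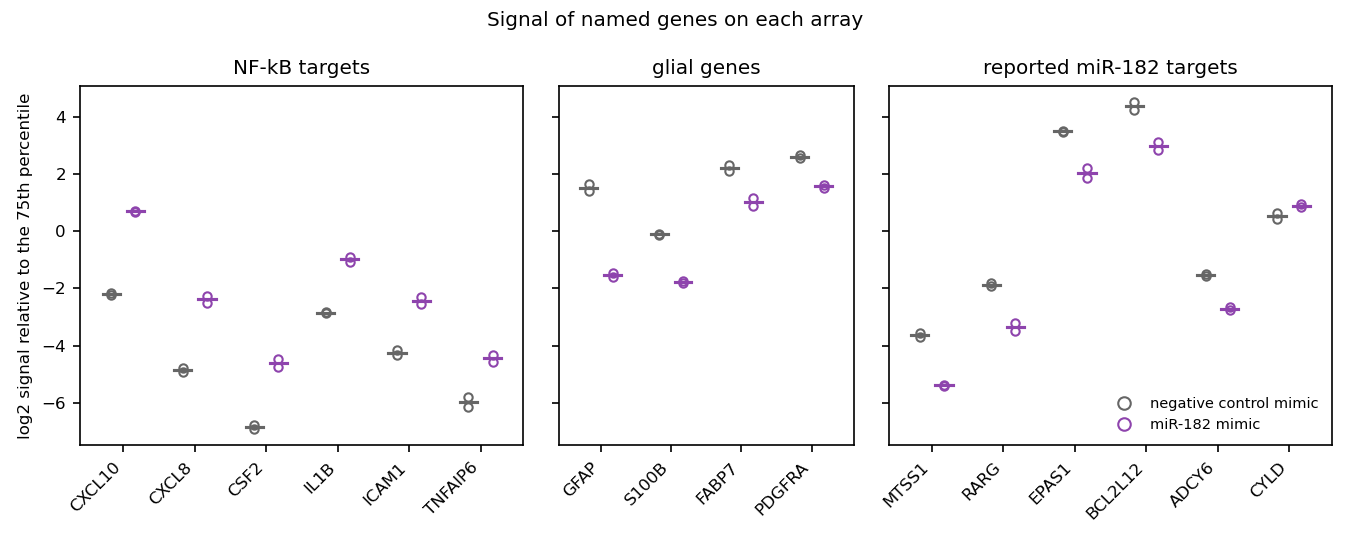
Log2 signal relative to each array's 75th percentile for NF-kB targets, glial genes and reported miR-182 targets; each circle is 1 array, grey for the negative control mimic and purple for the miR-182 mimic, and the bars are group means (n = 2). The 2 circles of a group lie close together beside the distance between the groups for GFAP (1.63 and 1.41 against -1.45 and -1.62), while CYLD was at 0.63 and 0.42 against 0.94 and 0.83.

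Among 38 interferon-stimulated genes 4 rose and 0 fell (2 were lower at an unadjusted p under 0.05), and the list median was 0.10. Those that rose were CXCL10, which the NF-kB list also holds, the chemokine gene CXCL11 (4.89-fold, 2.29 ± 0.15), the interferon gene IFNB1 (3.66-fold, 1.87 ± 0.24) and the exonuclease gene ISG20 (2.21-fold, 1.15 ± 0.13). The type III interferon gene IFNL1, outside the list and chosen after its values were seen, rose 4.11-fold (2.04 ± 0.16). Adjusted over the list alone, 5 were higher and 1 lower, and the list did not pass camera (adjusted p = 0.129). The fit called 1 member without control replicate 1 and 2 without control replicate 2.

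Of 21 glial and neural lineage genes measured, 4 fell and 0 rose (2 were higher at an unadjusted p under 0.05). The 2 other probes of GFAP gave -3.68 and -2.07. The calcium-binding protein gene S100B fell 3.16-fold (-1.66 ± 0.12), the fatty acid-binding protein gene FABP7 2.28-fold (-1.19 ± 0.16) and the growth factor receptor gene PDGFRA 2.04-fold (-1.03 ± 0.12). The stem cell transcription factor SOX2 (-0.78 ± 0.24, adjusted p = 0.160) and the intermediate filament gene NES (-0.13 ± 0.20, adjusted p = 0.758), both chosen after their values were seen, were not past the threshold, and NES had the opposite sign without control replicate 1 (0.0568) and without miR-182 replicate 2 (0.0439). The list median was -0.19 and the list did not pass camera (adjusted p = 0.151), and adjusted over the list alone 5 were lower and 2 higher. The fit called 1 member without control replicate 1, 1 without control replicate 2 and 2 without miR-182 replicate 1. Markers of other cell types had 0 calls among 15 measured by limma, with 7 at an unadjusted p under 0.05 and a median of 0.18 (camera adjusted p = 0.151); adjusted over the list alone, 5 were higher and 2 lower. They included the epithelial gene EPCAM (0.95 ± 0.15, adjusted p = 0.0593) and the endothelial gene KDR (0.93 ± 0.17), while the epithelial keratin KRT19 was at -0.58 ± 0.12 and the endothelial receptor TEK, below background in the controls, was at least 1.93-fold higher (adjusted p = 0.0619).

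TGF-beta targets, mesenchymal genes and hypoxia genes each had members that moved in both directions. Of 24 TGF-beta target genes 2 rose, among them the matricellular gene CCN2 (2.86-fold, 1.51 ± 0.17), and 2 fell, the helix-loop-helix inhibitors ID2 (-1.13 ± 0.15) and ID3 (-0.94 ± 0.12). Of 26 mesenchymal and invasion genes the urokinase receptor PLAUR (1.33 ± 0.15), its ligand PLAU (1.36 ± 0.19, chosen after its values were seen) and the receptor kinase AXL (0.91 ± 0.12) rose, and CHI3L1 (-1.67 ± 0.12) and the matrix cross-linking enzyme LOX (-0.90 ± 0.13) fell. Of 26 hypoxia genes ANGPTL4 (2.08 ± 0.16) and the carbonic anhydrase CA9 (1.20 ± 0.13) rose, and EPAS1 and LOX fell. Adjusted over the list alone, 4 were higher and 4 lower for TGF-beta targets, 5 and 2 for mesenchymal genes, and 7 and 4 for hypoxia genes. The medians were 0.08 for each of the 3 lists, with camera adjusted p of 0.896, 0.896 and 0.384; the mean of the mesenchymal list was -0.0017, opposite in sign to its median. Without control replicate 1 limma called 0 members of each of the 3 lists, with 8 at an unadjusted p under 0.05 in each, and without control replicate 2 it also called 0, with 7, 7 and 8. Without miR-182 replicate 1 it called 2 TGF-beta targets and 1 mesenchymal gene.

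Genes of the cell cycle and DNA repair showed no call by limma. Among 30 G1/S and DNA replication genes, 33 G2/M and mitosis genes and 25 homologous recombination genes the count was 0, with 9, 2 and 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Of the 9 G1/S genes at an unadjusted p under 0.05, 3 were higher, such as the kinase CDK6 (0.68 ± 0.13, adjusted p = 0.0710), and 6 lower, such as E2F2 (-0.79 ± 0.19, adjusted p = 0.107, second probe 0.02), cyclin CCND3 (-0.67 ± 0.17) and MCM6 (-0.45 ± 0.13). The mitotic cyclin CCNA2 was at 0.72 ± 0.16 (adjusted p = 0.0990) and the kinesin KIF11 at -0.37 ± 0.14 (second probe 0.27). The repair gene NBN was at 0.57 ± 0.13 (adjusted p = 0.0970, second probe -0.024), FANCD2 at -0.48 ± 0.12 (other probes -0.59 and 0.16) and BARD1 at -0.43 ± 0.13. The medians were -0.08, -0.0049 and 0.0072 (camera adjusted p = 0.755, 0.896 and 0.768). The G2/M mean was 0.02 and camera ranked that list upward, against the sign of its median, which was above 0 with quantile normalization (0.010), median scaling (0.00085) and normexp (0.025).

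The other lists did not pass camera either. Of 26 FOXO target genes 1 fell, the sestrin SESN3 (-1.40 ± 0.16, adjusted p = 0.0393), and the median was -0.14 (camera adjusted p = 0.755). Among 24 p53 target genes limma called 0 and 8 had an unadjusted p under 0.05, among them PMAIP1 (1.20 ± 0.21, adjusted p = 0.0661); the median was 0.0027, -0.020 with normexp, and camera ranked the list downward (adjusted p = 0.999). BIRC3 rose and BCL2L12 fell among 30 apoptosis regulators (median 0.07, camera adjusted p = 0.755). The stress transcription factor ATF3 rose (1.07 ± 0.12, adjusted p = 0.0374), as the sole call of 29 unfolded protein and integrated stress response genes (median 0.06, camera adjusted p = 0.530), and the syntaxin STX3 (1.07 ± 0.13, adjusted p = 0.0411) as that of 25 vesicle trafficking genes (median -0.07, camera adjusted p = 0.896). MTSS1 was the sole call of 29 actin and adhesion genes, whose median was -0.17 (camera adjusted p = 0.0939) and which included the actin-severing gene CFL1 at -1.46 ± 0.25 (adjusted p = 0.0620). Limma called 0 of 24 cholesterol genes (8 at an unadjusted p under 0.05, median 0.09, camera adjusted p = 0.255) and 0 of 19 microRNA pathway genes (5 at an unadjusted p under 0.05, median -0.03, camera adjusted p = 0.896), with TNRC6C at 0.73 ± 0.13, AGO2 at 0.62 ± 0.12 and AGO1 at -0.88 ± 0.16, whose second probe gave 0.38. Adjusted over the list alone, the counts higher and lower were 3 and 4 for FOXO targets, 3 and 2 for p53 targets, 3 and 3 for apoptosis, 1 and 0 for the stress response, 1 and 0 for vesicle trafficking, 1 and 4 for actin, 0 and 0 for cholesterol, and 2 and 1 for the microRNA pathway. The 20 housekeeping genes gave 0 calls by limma (2 at an unadjusted p under 0.05, 0 adjusted over the list alone) and log2 fold changes from -0.38 to 0.36, with a median of -0.03 that was 0.0056 with quantile normalization (camera adjusted p = 0.886).

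**Figure D3:**
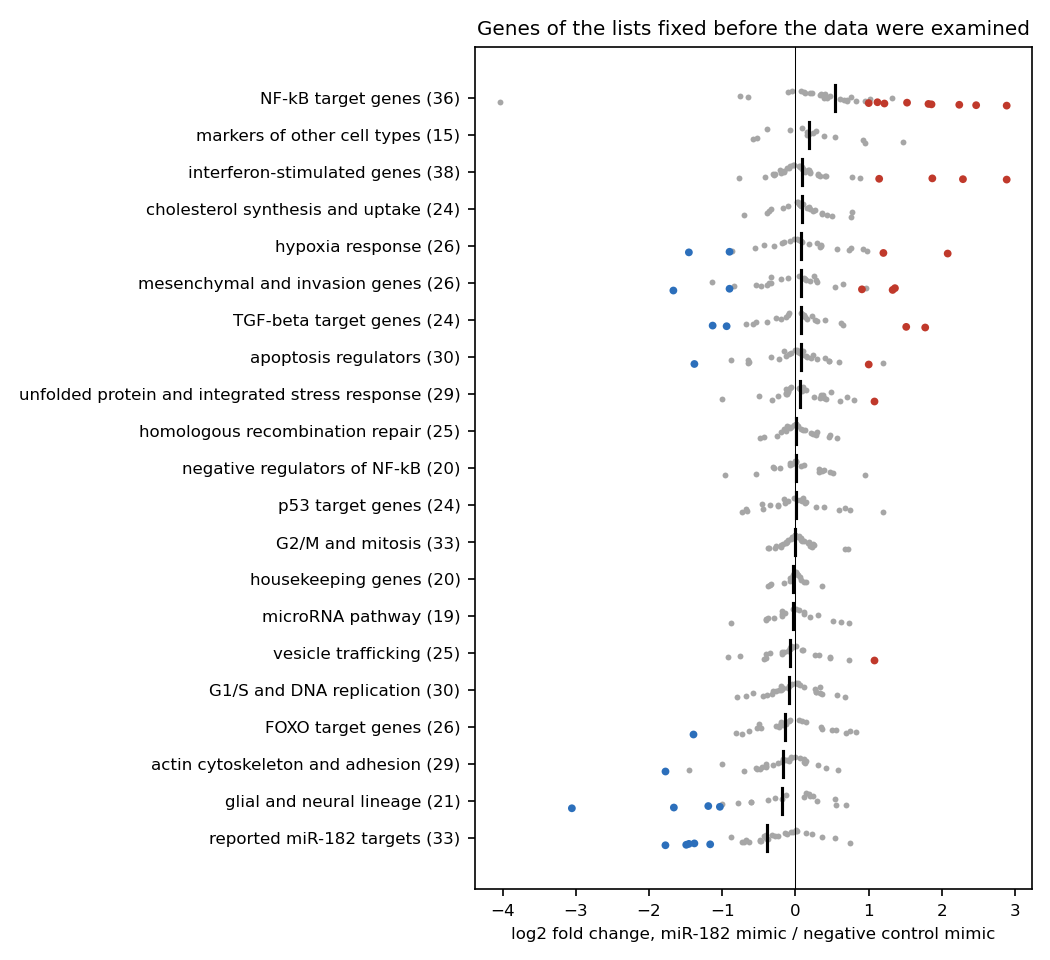
Log2 fold change, miR-182 mimic over negative control mimic, of each measured member of the 21 gene lists, with the number measured in brackets and lists ordered by median (black bars); red points rose, blue points fell and grey points did not pass the threshold. NF-kB target genes had the highest median (0.54) and reported miR-182 targets the lowest (-0.39); CXCL1 and TEK, below background in 1 group, are drawn at their fitted value.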

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

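The replacement of the mean by the median spot signal in normexp was chosen after seeing the data; the other settings were not. Against 702 calls, limma called 0 genes with no filter on dim probes (31758 tested, 4904 at an unadjusted p under 0.05), 0 with an unmoderated model (4318) and 0 at an adjusted p under 0.01 (5363). The second has fewer degrees of freedom; for the first the cause was not tested. Leaving out 1 array gave 42 to 1051 calls, the lone sample being assumed to vary like the other group. Testing each probe on its own gave 488 calls among 31238 probes, a count of probes and not of genes. Apart from the replicate block, given below, the other settings gave 531 to 965 genes. Normexp on the median spot signal with quantile normalization, 3 choices changed together, called 908, of which 427 rose, and shared 513 with the 702. All 702 kept their direction in every setting that tested them by gene, but many settings could not change it. The variance models and the replicate block leave the fold change as it is, and the filters leave that of a given probe. Leaving out 1 array cannot reverse a gene whose groups are separate, as in all 702. The kept direction is thus informative only for the normalizations and the mean of a gene's probes. The replicate block gave 2843 calls (1355 higher, 1488 lower), including all 702; same-numbered arrays deviated together at r = 0.50 across genes, but 2 pairs and the labels do not show that the numbers pair the samples. Of 134 genes followed by name through the settings 75 were called, and 0 of these reversed in any setting, though many settings could not reverse them. Some genes named in this report, such as IL12A, MET and ERBB3, were not among the 134. All 75 lost the call with no filter and with the unmoderated model, 12 with normexp, 8 with the mean of a gene's probes and 3 with median scaling. ITCH reversed with the mean of probes (-0.0232), which averages 2 probes of opposite sign, and NES, at -0.317 to 0.0568 with 1 array left out, without control replicate 1 (0.0568) and without miR-182 replicate 2 (0.0439); the cause was not tested. Of the lists, 0 passed camera with an estimated correlation (adjusted p = 0.537 for reported targets and 0.537 for NF-kB targets), which also missed the shifted list in the simulation. With fry 4 passed, which adds interferon-stimulated genes (0.0201) and glial genes (0.0493). Leaving out 1 array gave adjusted p of 1.45e-04 to 0.00176 for reported targets and 3.39e-11 to 6.58e-08 for NF-kB targets. Camera also passed interferon-stimulated genes with normexp (0.00781), actin genes with no filter (0.0353) and glial genes without control replicate 2 (0.0118). A slide block was not run, since 1 slide held all arrays, nor was the seed-site shift with its alternatives. Dim signal limits the 32 rises and 21 falls that have only a bound.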

Other observations

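The families by symbol prefix, the genes named from them and in the next paragraph, and the tests of interferon-stimulated genes and of the glial genes other than GFAP were chosen only after the results were seen. Of 54 genes whose symbol starts with IL, interleukins and their receptors, 9 rose and the median log2 fold change was 0.35, or 0.18 with normexp, where 8 rose and 1 fell. This was the smallest p of 260 families by camera with a preset correlation (adjusted p = 1.16e-04), and the call was lost with an estimated correlation (adjusted p = 0.983). None of the 260 families passed with an estimated correlation. That can come from a test that misses shifts or from families that did not shift, and no family was simulated. The loss therefore leaves open whether the family shifted. Outside the NF-kB list 51 remain, of which 7 rose, with a median of 0.30. They include IL11, the cytokine IL24 (2.21 ± 0.16, second probe 1.51), IL12A (1.22 ± 0.12), IL7 (0.87 ± 0.12) and the receptors IL15RA (1.11 ± 0.12) and IL1R1 (0.85 ± 0.12). Without control replicate 1 limma called 2 of the 54, without control replicate 2 it called 1, and without miR-182 replicate 1 it called 4. Of 11 CC chemokines CCL25 and CCL26 rose (median 0.43, adjusted p = 0.0202, and adjusted p = 0.983 with an estimated correlation). Limma called 0 of them without control replicate 1, miR-182 replicate 1 or miR-182 replicate 2 (4, 7 and 5 at an unadjusted p under 0.05) and 1 without control replicate 2. With normexp it called 1, at a median of 0.26, and with the mean of a gene's probes 0 (6 at an unadjusted p under 0.05). Of 24 cilia and flagella associated genes 4 rose, such as CFAP45 at 1.66 ± 0.15 (median 0.14, adjusted p = 0.0387, and adjusted p = 0.983 with an estimated correlation). Limma called 0 of these without control replicate 1 and 0 without control replicate 2, with 6 and 7 at an unadjusted p under 0.05. Their median was 0.09 with normexp, 0.25 without control replicate 1 and 0.28 without miR-182 replicate 1, and 2 were called with the mean of a gene's probes. SOX transcription factors did not pass (median -0.46 over 16 genes, adjusted p = 0.0561), with 2 that fell, SOX6 and SOX21, and 1 called without control replicate 1, control replicate 2 or miR-182 replicate 1, or with the mean of a gene's probes. The SOX median was -0.30 without miR-182 replicate 1 and -0.71 without miR-182 replicate 2. Each family median kept its sign under every scaling. Lists matched on signal were not drawn for the families, so a bias of probes at their signal level was not tested.

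Other genes with called changes were picked for their values, and no theme was tested. CGA, the alpha subunit of glycoprotein hormones, rose 3.75-fold (1.91 ± 0.13, second probe 1.77) and PLAC1 rose 2.90-fold (1.54 ± 0.13). Of 7 pregnancy-specific glycoprotein genes measured, 4 rose from low signals, PSG6 (1.53 ± 0.12), PSG8 (1.59 ± 0.14, second probe 0.80), PSG9 (1.12 ± 0.14, second probe 0.76) and PSG1 (at least 2.72-fold). Limma called 1 of the 7 without control replicate 1 and 1 without control replicate 2, and with normexp it called 2, the median of the 7 going from 1.12 to 0.36. These genes are near-identical copies, so which of them gave the signal is uncertain. The receptor genes ERBB4 (-1.24 ± 0.13), FGFR1 (-1.04 ± 0.12, other probes -1.05 and -1.33), FGFR2 (-0.92 ± 0.13, second probe -0.59) and ALK (-2.32 ± 0.27, well above background on 1 of the 2 miR-182 arrays) fell. PDGFRA also fell (-1.03 ± 0.12), whereas AXL rose (0.91 ± 0.12), and MET (0.03 ± 0.14), IGF1R (-0.28 ± 0.16) and ERBB3 (-0.26 ± 0.18) did not pass the threshold. The astrocyte membrane gene MLC1 fell 3.92-fold (-1.97 ± 0.25) and the receptor phosphatase gene PTPRZ1 3.26-fold (-1.70 ± 0.20). MYD88, the adaptor of Toll-like and interleukin-1 receptors, fell 2.62-fold (-1.39 ± 0.16, second probe -1.38), and the membrane raft gene FLOT1 2.65-fold (-1.41 ± 0.12, second probe -1.45).

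The first pattern weighed was the set of 901 genes that differ at least 2-fold. A linear gradient along the slide predicts a slope near 0.5 of the step between neighbouring arrays of a group on the group difference, and the slope was -0.0324 (95% interval -0.0510 to -0.0138). Unequal labelling or hybridization predicts shifted spike-ins, but the 8 control RNAs well above background differed by at most 0.137 log2 units in size. The slope argues against the gradient, and the spike-ins argue against an unequal labelling or hybridization that remains after the scaling. A difference shared by spike-ins and genes is removed by the scaling. The quality of the sample RNA was not tested. A non-linear effect of position stays open, because position and group cannot be told apart.

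The second pattern was the rise of NF-kB targets. A bias of probes at their signal level is argued against by 10000 lists matched on mean signal, among which the list median lay at percentile 100. A broad interferon response to transfected RNA, as the whole cause, predicts interferon-stimulated genes near the NF-kB median of 0.54, and the 37 outside that list had a median of 0.0952 (95% bootstrap interval -0.0367 to 0.180). The test bears only on a response that raises both lists alike. A smaller interferon component, or a response to transfected RNA that raises the 2 lists unequally, stays open. The interferon list lay at percentile 99.48 of its own matched lists, and IFNB1 (1.87), IFNL1 (2.04) and CXCL11 (2.29) rose. An effect of the miR-182 mimic on NF-kB signalling remains a hypothesis, with array position also open; CYLD (0.36 ± 0.14) showed no fall in its RNA, and protein was not measured here.

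The third pattern was the fall of GFAP, S100B, FABP7 and PDGFRA, in a glial list of 21 that did not pass camera (adjusted p = 0.151, and 0.640 as an adjusted p with an estimated correlation) and had 9 members above 0. Fewer glial cells in the culture would lower every glial gene about as GFAP, whose upper 95% bound was -2.67. The other 20 genes of this glial and neural lineage list had a median of -0.160 (95% bootstrap interval -0.601 to 0.190). This comparison cannot decide the question, because GFAP was named for the size of its fall. A median of the other genes above its bound therefore says little. The cells were also an established glioma line, so by design the culture held no other cell type. For the median of the whole list, a bias of probes at this signal level stays open. That median lay at percentile 1.58 of matched lists, between the bounds set for and against it. Matched lists were not drawn for the genes that fell. The miR-182 mimic as the origin of the fall is untested beyond the comparison itself.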
